A study of Caenorhabditis elegans with 24 samples.

How the data were processed

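Whole young adult worms were lysed in Trizol, total RNA was purified with a miRNeasy Micro kit and libraries were made with SMART-Seq2, per the labels' protocols. SMART-Seq2 reverse-transcribes full-length polyadenylated transcripts and does not mark their strand. The values used here are those the authors deposited, which are regularized log2 (rlog) values of normalized counts per the file name, 1 value per gene and library, with all 24 libraries on 1 scale. The tools bcl2fastq 2.20 and kallisto 048.0 and the build WBcel235 are named, with no role or order, per the submitters' processing notes. The tool that made the rlog values, its settings, any filter and any batch correction are not given in the sources used here. The rlog transformation shrinks the differences of genes with few reads, so differences of genes with low values are understated, and the deposited values hold no read counts. Depth is therefore unknown, no counting interval or detection limit was computed, and count-based tests were not run.

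Each library was assigned to its genotype by its label, with 4 libraries in each of 6 groups. The replicate number in the labels equals the batch label, and each of 4 batches holds 1 library of every group, so the numbers pair libraries through a labelled batch. What a batch shares, and whether the 4 libraries of a group came from separate cultures, is not given in the sources used here, so p-values measure the spread between these libraries. Deviations from the group means had a mean correlation across genes of 0.0504 between libraries of the same batch in different groups and of -0.0163 between different batches. For daf-2 and wt the same-batch correlations were 0.403 to 0.513, while for the other pairs of groups some were below 0. No library was a duplicate: the correlation across genes was 0.949 to 0.991 in the 36 pairs within groups and 0.781 to 0.984 in the 240 pairs between groups, and the smallest root mean square difference was 0.357 within and 0.501 between groups.

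The file held 21689 WormBase gene identifiers, all of which had a position in the WBcel235 annotation (Ensembl release 115), the build the submitters name. A symbol was found for 20315 of them, and the 1374 others (6.34%) are printed by identifier. Genes with a mean value of at least 3 over the 24 libraries were tested (14482 genes). A linear model with 1 mean per group was fitted to all 24 libraries with limma 3.58.1 in R 4.3.3, with 18 residual degrees of freedom, an intensity trend in the prior variance and no batch term. The 6 pairwise contrasts and the 2 differences of the htz-1 effect between backgrounds were tested 2-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A gene's adjusted p is from this limma fit unless a setting is named.

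Lists of genes (29, of which 28 had tested members) were written from general knowledge before the data were examined, together with the groups, the comparisons, the tests and the alternative settings listed below. They cover DAF-16 targets, insulin signalling, H2A.Z deposition, histones, stress, immunity, metabolism, growth and markers of tissues, germline and embryos. The list of mitochondrially encoded genes had no member in the values. Lists were tested against the other genes with camera (limma, preset inter-gene correlation 0.01), adjusted over the lists of a contrast. Members were also counted after adjustment over the list alone. Camera with an estimated correlation kept 1 of the 95 list calls, that of DAF-16-induced genes in daf-2 against wt. The fry test, which asks whether a list's genes move on balance in a direction without comparing them with other genes, kept 70.

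Genes were named by a rule. It took htz-1, daf-2 and daf-16 in every group and sod-3, mtl-1, hsp-12.6, dod-17 and ins-7 in every comparison. In each pairwise comparison it took the 6 largest rises and the 6 largest falls among called genes whose groups did not overlap, and in each difference of the htz-1 effect the 4 largest positive and 4 largest negative values. Of each list it took up to 2 called members per direction with the smallest p, and some of these are printed as examples. This last part was applied only to lists with a camera call, in both directions for the DAF-16 lists and in the direction of the call for the others.

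Alternatives planned beforehand were batch as a block, no filter on low values, a minimum mean of 5, centring each library on its median, quantile normalization, no intensity trend, robust variance, array weights, a fit of only the groups compared, each batch and each library left out in turn, and an estimated correlation and fry for lists. Correlations were set beside 100 simulations of unchanged groups, overlaps beside those of independent lists, and both, where libraries are shared, beside values with these split. Chosen after seeing the data were the removal of wt 1 and daf-2 1 together, the removal of single libraries from list tests, the comparison of the daf-16 effect with the htz-1 effect, and the contrast of daf-16;daf-2 with wt. No value column was left out.

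The model was tested on simulated data with 14482 genes, 50 of them changed at each of 4 sizes. For htz-1 against wt, 16% of genes changed by 0.5, 46% by 1, 88% by 2 and 100% by 4 log2 units were recovered, with 10 false among 135 calls. For the difference of the htz-1 effect between the daf-2 and wt backgrounds, 0%, 24%, 70% and 98% were recovered, with 9 false among 105 calls.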

Results

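RNA was measured by sequencing in whole young adult Caenorhabditis elegans on the first day of adulthood, grown at 20 °C on OP-50-1 bacteria. The 24 libraries fell into 6 genotypes of 4 libraries each, the wild-type strain N2 (wt), daf-2, daf-16;daf-2, htz-1, daf-2;htz-1 and daf-16;daf-2;htz-1, with the alleles e1370 of daf-2, mu86 of daf-16 and bon101 of htz-1. The gene daf-2 encodes the insulin/IGF-1 receptor, whose reduced function extends lifespan through the FOXO transcription factor encoded by daf-16. The gene htz-1 encodes the histone variant H2A.Z, which replaces H2A in nucleosomes. Each of 4 labelled batches held 1 library of each genotype. The values were regularized log2 values for 21689 genes, between -2.01 and 19.7, and the number of reads behind them is unknown. The first principal component, with 60.3% of the variance, parted the 12 libraries with the htz-1 allele from the 12 without it.

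**Figure D1:**
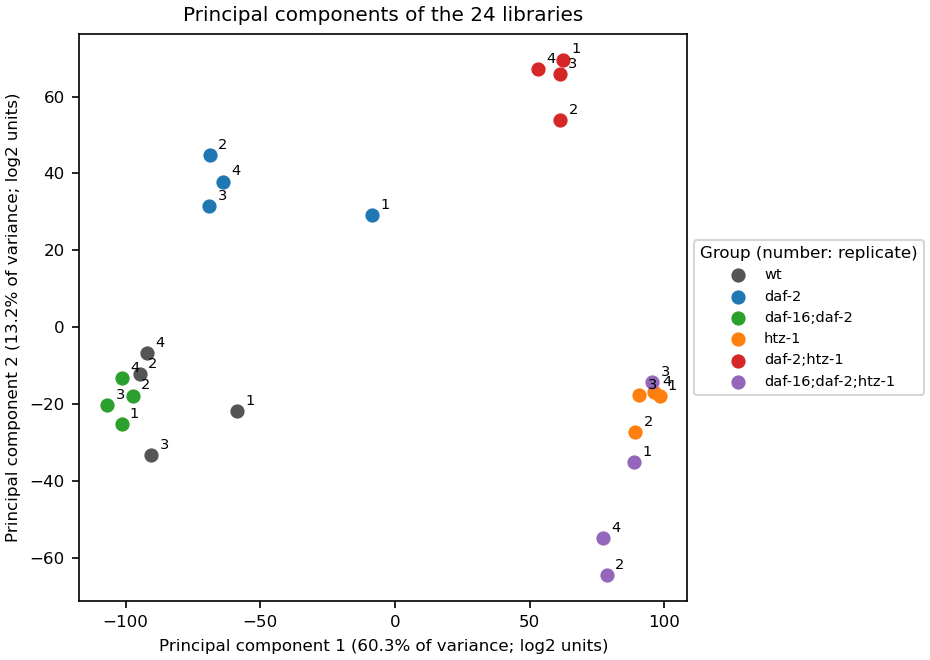
Principal components 1 (horizontal axis) and 2 (vertical axis) of the 24 libraries in log2 units, computed over the genes tested, with 1 point per library, coloured by genotype and numbered by replicate. The htz-1 libraries lie on the right of component 1, daf-2 replicate 1 lies nearer to them than the other daf-2 libraries, and daf-16;daf-2;htz-1 replicate 3 lies among the htz-1 libraries.

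The transcript of htz-1 (WBGene00019947, chromosome IV, 4446216 to 4446999 of WBcel235) was not lower in the libraries with the htz-1 allele. Its value was 10.91 ± 0.32 in wt and 10.81 ± 0.13 in daf-16;daf-2, against 11.37 ± 0.13 in htz-1, 11.33 ± 0.03 in daf-2;htz-1 and 11.43 ± 0.22 in daf-16;daf-2;htz-1 (mean ± SD, n = 4 each), and daf-2 differed from wt by 0.09. The htz-1 minus wt difference was 0.47 ± 0.16 (SE), adjusted p = 0.0155, a call that ended without batch 2 or 3, wt 2 or 3, or htz-1 4 (values from 0.37 to 0.41). What bon101 changes in the gene is not given in the sources used here, so these values do not check the labels. The daf-2 transcript (WBGene00000898, chromosome III, 2994514 to 3040846) lay between 6.47 ± 0.44 and 6.82 ± 0.28 in the 6 groups. The daf-16 transcript (WBGene00000912, chromosome I, 10750498 to 10776703) was 10.74 ± 0.35 in wt, 10.32 ± 0.11 in daf-2 and 9.87 ± 0.13 in daf-16;daf-2, where the difference from daf-2 was -0.45 ± 0.21 (SE), adjusted p = 0.109, but called with array weights (-0.51) and in a fit of only these 8 libraries (-0.45). It was 9.91 ± 0.24 in htz-1, 10.17 ± 0.17 in daf-2;htz-1 and 9.32 ± 0.57 in daf-16;daf-2;htz-1, where the difference from daf-2;htz-1 was -0.85 ± 0.21 (SE), adjusted p = 0.00276. A single value per gene does not show which part of the daf-16 transcript was measured.

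**Figure D2:**
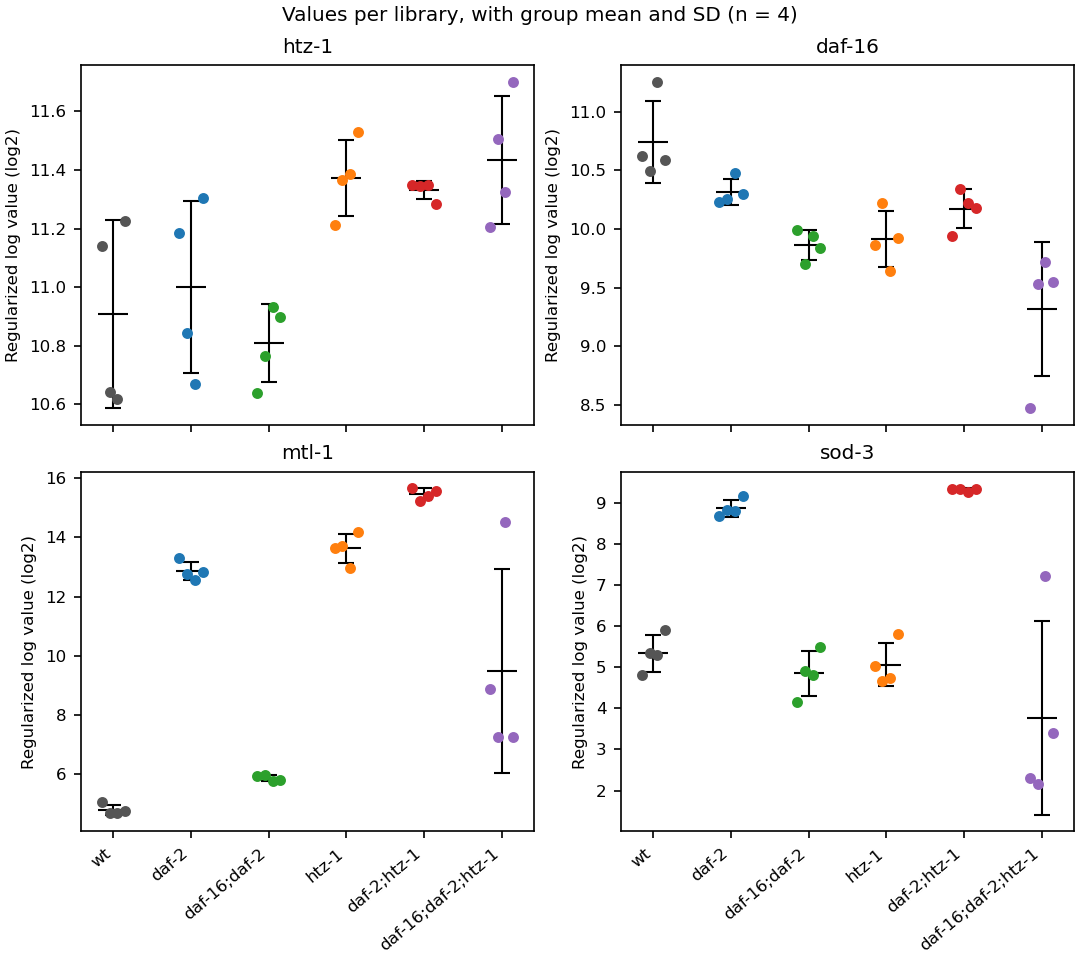
Regularized log2 values of htz-1, daf-16, mtl-1 and sod-3 in each library (points, coloured by genotype), with the group mean and SD (n = 4, black lines). In daf-16;daf-2;htz-1, mtl-1 reached 14.51 and sod-3 7.23 in replicate 3, above the other 3 libraries of that group.

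Some of the named values are uncertain. The library type does not mark strand, and the genes sod-3, clec-3, clec-210, clec-266, daf-36, aqp-1, akt-1, epg-2, tnc-2, sdz-24, cpg-3, egg-3, col-147, oac-20, gst-32, pho-1, flp-1 and his-47 overlap a coding gene on the opposite strand. Major sperm protein genes, core histone genes and the hsp-16.48 pair have near-identical copies whose reads could be shared.

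The comparison of daf-2 with wt asked which transcripts respond to reduced insulin/IGF-1 receptor function. The metallothionein gene mtl-1 (WBGene00003473, chromosome V, 6691371 to 6691863) rose from 4.81 ± 0.18 in wt to 12.87 ± 0.32 in daf-2 (SD, n = 4), by 8.06 ± 0.88 (SE), adjusted p = 5.6e-07. The mitochondrial superoxide dismutase gene sod-3 (WBGene00004932, chromosome X, 17092753 to 17094306), a classical DAF-16 target, rose by 3.54 ± 0.65 (SE), adjusted p = 5.3e-04. Genes known to be lower in daf-2 mutants fell, among them dod-17 (WBGene00010745, chromosome IV, 12976303 to 12978343, -2.40 ± 0.34 (SE), adjusted p = 2.7e-05) and dod-24 (-3.48). Of 14482 genes tested, 931 were higher and 862 lower in daf-2 (limma, adjusted p below 0.05), and 546 and 480 of these by at least 1 log2 unit. The small heat shock gene hsp-12.6 (0.14, adjusted p = 0.865) and the insulin-like peptide gene ins-7 (-0.23, adjusted p = 0.830) were not called.

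Among 30 DAF-16-induced genes, 16 rose and 1 fell (20 and 1 adjusted over the list alone, camera adjusted p = 4.9e-13, adjusted p = 0.0490 with an estimated correlation). They included dod-3 (5.48) and the long non-coding RNA tts-1 (5.25), and the member that fell was daf-36 (-0.71), an oxygenase gene of dafachronic acid synthesis, a call that ended without batch 1 or 4, daf-2 1, 3 or 4, or wt 2 or 4, and with wt 1 and daf-2 1 left out and a fit of only these 8 libraries (values from -0.71 to -0.61). For DAF-16-repressed genes (17 tested), 0 rose and 7 fell (0 and 7 adjusted over the list alone, camera adjusted p = 2.2e-05, adjusted p = 0.0896 with an estimated correlation). Of the 33 muscle genes tested, 0 rose and 12 fell (0 and 17 adjusted over the list alone, camera adjusted p = 3.4e-08, adjusted p = 0.403 with an estimated correlation). The troponin C gene tnc-2 (-1.11) and the troponin T gene tnt-3 (-0.99) fell. Among 30 intestine genes, 2 rose and 12 fell (2 and 17 adjusted over the list alone, camera adjusted p = 2.7e-05, adjusted p = 0.695 with an estimated correlation). The cysteine protease genes cpr-1 (-2.18) and cpr-5 (-2.63) fell. For sperm genes (88 tested), 1 rose and 10 fell (1 and 21 adjusted over the list alone, camera adjusted p = 1.0e-08, adjusted p = 0.747 with an estimated correlation). Without daf-2 replicate 1 the median of the list was -0.29 instead of -0.69, adjusted p = 0.00230. An example was ssp-37 (-0.87). The mean of the collagen list in daf-2 replicate 1 stood apart from the other daf-2 libraries (8.38 against a median of 9.59).

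Of the 20 insulin-like peptide genes tested, 4 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.0343, adjusted p = 0.747 with an estimated correlation). Here ins-11 rose by 3.80 and ins-23 by 3.98. Among 62 superoxide dismutase, catalase and phase II genes, 12 rose and 4 fell (16 and 6 adjusted over the list alone, camera adjusted p = 0.0226, adjusted p = 0.747 with an estimated correlation). The dismutase gene sod-5 (2.19) and the glutathione S-transferase gene gst-20 (1.17) rose. For early embryo genes (21 tested), 3 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.00810, adjusted p = 0.695 with an estimated correlation). The zygotic gene sdz-24 rose by 3.78. Also called by camera, with numbers of higher and lower members, were proteasome subunit (0 and 1 of 33, 0 and 1 adjusted over the list alone, camera adjusted p = 0.00692), endoplasmic reticulum (ER) chaperone and sensor (0 and 4 of 20, 0 and 4 adjusted over the list alone, camera adjusted p = 0.0343) and ribosomal protein (0 and 2 of 78, 0 and 1 adjusted over the list alone, camera adjusted p = 2.4e-04) genes. These calls had adjusted p = 0.919, 0.770 and 0.919 with an estimated correlation. Of 28 lists camera called 11, of which calls ended with a minimum mean of 5 (early embryo), no filter on low values (insulin-like peptide), centring (ER), quantile normalization (ER, insulin-like peptide), wt 1 and daf-2 1 left out (insulin-like peptide) and 1 library left out (ER, superoxide dismutase, insulin-like peptide, proteasome, ribosomal).

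The largest rises among genes whose 4 daf-2 libraries all lay above the 4 wt libraries were cpr-2 (9.46), clec-18 (8.87), H39E23.3 (8.75), F56D6.9 (8.10), mtl-1 (8.06) and F45D11.14 (7.46), of which cpr-2 encodes a cathepsin B-like protease and clec-18 a C-type lectin-domain protein. The largest falls were clec-10 (-6.28), F56A4.3 (-5.09), F55G11.2 (-5.04), F56A4.10 (-5.02), irld-35 (-4.82) and clec-210 (-4.35). The counts were 432 and 318 when only these 8 libraries entered the fit, and as low as 512 higher without batch 2 and 438 lower without batch 4.

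The comparison of daf-16;daf-2 with daf-2 asked which of the transcripts depended on DAF-16. The values of mtl-1 (-6.99 ± 0.88 (SE), adjusted p = 3.1e-06) and sod-3 (-4.02 ± 0.65 (SE), adjusted p = 8.2e-05) fell, and dod-17 rose by 4.30 ± 0.34 (SE), adjusted p = 3.1e-09. The invertebrate lysozyme gene ilys-5 rose by 4.71. In all, 2319 genes were higher and 1397 lower in daf-16;daf-2, 1464 and 659 of them by at least 1 log2 unit. The genes hsp-12.6 (-0.69, adjusted p = 0.229) and ins-7 (0.84, adjusted p = 0.262) were not called.

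Of the 30 DAF-16-induced genes tested, 1 rose and 17 fell (2 and 19 adjusted over the list alone, camera adjusted p = 2.5e-10, adjusted p = 0.0603 with an estimated correlation). Falls were measured for tts-1 (-5.28) and dod-3 (-4.36), and daf-36 rose by 0.98. Among 17 DAF-16-repressed genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 1.1e-06, adjusted p = 0.0603 with an estimated correlation). The member that fell was the guanylyl cyclase gene gcy-18 (-1.21), a call that ended without batch 1, 3 or 4, daf-2 1 or 3, or daf-16;daf-2 2, 3 or 4, and with quantile normalization, wt 1 and daf-2 1 left out and a fit of only these 8 libraries (values from -1.30 to -0.84). For innate immunity genes (198 tested), 76 rose and 38 fell (84 and 42 adjusted over the list alone, camera adjusted p = 0.00437, adjusted p = 0.551 with an estimated correlation). Of the 30 intestine genes tested, 21 rose and 1 fell (23 and 2 adjusted over the list alone, camera adjusted p = 6.7e-08, adjusted p = 0.407 with an estimated correlation). The vacuolar ATPase gene vha-6 (1.40) and cpr-1 (1.85) rose. Among 33 muscle genes, 14 rose and 0 fell (20 and 0 adjusted over the list alone, camera adjusted p = 2.1e-06, adjusted p = 0.443 with an estimated correlation). Examples were tnc-2 (1.35) and the troponin I gene tni-1 (1.40). For sperm genes (88 tested), 42 rose and 0 fell (55 and 1 adjusted over the list alone, camera adjusted p = 5.0e-10, adjusted p = 0.551 with an estimated correlation). The median of the list, 0.99, was 0.57 without daf-2 replicate 1, adjusted p = 8.0e-06. They included nspd-7 (1.36) and the major sperm protein gene msp-49 (1.48, a call that ended without batch 1 (0.85)). Of the 78 ribosomal protein genes tested, 25 rose and 0 fell (33 and 0 adjusted over the list alone, camera adjusted p = 1.6e-08, adjusted p = 0.723 with an estimated correlation).

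Among 20 insulin signalling genes, 2 rose and 7 fell (2 and 8 adjusted over the list alone, camera adjusted p = 0.0182, adjusted p = 0.580 with an estimated correlation). The kinase genes akt-1 (-0.63) and akt-2 (-1.22), which act between DAF-2 and DAF-16, fell. For insulin-like peptide genes (20 tested), 1 rose and 7 fell (1 and 8 adjusted over the list alone, camera adjusted p = 0.00176, adjusted p = 0.503 with an estimated correlation). Of the 48 oogenesis and germline genes tested, 0 rose and 6 fell (0 and 4 adjusted over the list alone, camera adjusted p = 1.0e-03, adjusted p = 0.762 with an estimated correlation). The eggshell proteoglycan gene cpg-3 (-1.47) and the egg activation gene egg-3 (-0.62) fell. Camera also called, with numbers of higher and lower members, histone (15 and 1 of 59, 15 and 1 adjusted over the list alone, camera adjusted p = 0.0232), early embryo (1 and 6 of 21, 1 and 6 adjusted over the list alone, camera adjusted p = 0.00949), autophagy and lysosome (1 and 4 of 28, 0 and 4 adjusted over the list alone, camera adjusted p = 0.0266) and DNA replication and cell cycle (0 and 1 of 34, 0 and 0 adjusted over the list alone, camera adjusted p = 0.0338) genes. None was kept with an estimated correlation (adjusted p = 0.762, 0.506, 0.407 and 0.771). Camera called 14 of 28 lists, and calls ended with a minimum mean of 5 (histone, early embryo), wt 1 and daf-2 1 left out (autophagy, DNA replication) and 1 library left out (autophagy, DNA replication, histone).

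The largest rises with separate groups were F55G11.2 (7.02), clec-10 (6.14), dod-22 (5.92), dod-24 (5.50), oac-32 (5.35) and oac-20 (5.0), and the largest falls were cpr-2 (-9.40), H39E23.3 (-8.90), clec-18 (-8.86), F45D11.14 (-8.51), F56D6.9 (-7.89) and R05H10.7 (-7.37). Without daf-2 replicate 1 the counts were 1283 and 891, and without daf-16;daf-2 replicate 3 they were 1440 and 913. The split of 2319 higher and 1397 lower depended on scaling, with 1671 and 2073 when each library was centred on its median (which moved the median of all genes by -0.16) and 1911 and 2009 with quantile normalization.

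Most genes called in daf-2 moved back in daf-16;daf-2. Of the 931 genes higher in daf-2 than in wt, 706 were lower in daf-16;daf-2 than in daf-2 (89.8 expected for independent lists), and of the 862 lower genes, 721 were higher (138 expected). Both comparisons use the daf-2 libraries, which alone gives opposed values. The correlation across genes was -0.85, against a mean of -0.46 for simulated unchanged groups, and the covariance was -0.51 against -0.05. With the daf-2 libraries split into 2 and 2, the mean correlation was -0.66, and 338 and 338 genes were called in both on average (35.7 and 58.7 expected for independent lists). Genes are not independent replicates, so these values describe the gene set only.

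The comparison of htz-1 with wt asked which transcripts differ where the H2A.Z gene is mutated. The hatching protease gene hch-1 (WBGene00001828, chromosome X, 14696411 to 14699977) rose from 2.16 ± 0.13 to 10.83 ± 0.43 (SD, n = 4), by 8.68 ± 0.65 (SE), adjusted p = 1.7e-10. The C-type lectin-domain gene clec-266 (chromosome X, 6617393 to 6622915) rose by 9.0 ± 0.51 (SE), adjusted p = 2.6e-12, and the collagen gene dpy-14, used in the first cuticle, by 8.50 ± 0.58 (SE), adjusted p = 3.6e-11. Of the genes tested, 3830 were higher and 3552 lower in htz-1, 2414 and 2360 of them by at least 1 log2 unit. Of the DAF-16 target genes fixed beforehand, mtl-1 rose by 8.82 ± 0.88 (SE), adjusted p = 9.7e-09, while sod-3 differed by -0.28 ± 0.65 (SE), adjusted p = 0.748, and dod-17 fell by 1.68, adjusted p = 2.1e-04. The daf-16 transcript fell by 0.83, adjusted p = 0.00165. The value of ins-7 was 1.31, adjusted p = 0.0484, a call that ended without batch 1, 3 or 4, wt 1 or 3, or htz-1 1, 3 or 4, and with no filter on low values, no intensity trend, array weights, wt 1 and daf-2 1 left out and a fit of only these 8 libraries (values from 0.68 to 1.40), and hsp-12.6 was not called (-0.54).

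Among 88 sperm genes, 0 rose and 84 fell (0 and 84 adjusted over the list alone, camera adjusted p = 2.8e-31, adjusted p = 0.332 with an estimated correlation). The major sperm protein genes msp-59 (-4.17) and msp-65 (-4.37) were examples, and the list median was -3.42. For collagen genes (131 tested), 17 rose and 87 fell (18 and 89 adjusted over the list alone, camera adjusted p = 2.5e-10, adjusted p = 0.600 with an estimated correlation). The cuticle collagen genes col-129 (-6.95) and col-81 (-6.75) fell, and the list median was -2.08 (-1.0 with no filter on low values). Of the 59 core and linker histone genes tested, 37 rose and 1 fell (37 and 1 adjusted over the list alone, camera adjusted p = 1.7e-10, adjusted p = 0.332 with an estimated correlation). The linker histone-like gene hil-7 (6.39) and the core histone gene his-61 (3.46) rose. Among 21 early embryo genes, 12 rose and 2 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.00164, adjusted p = 0.416 with an estimated correlation). They included the proneural factor gene lin-32 (4.4) and sdz-28 (3.70). For hypodermis and seam genes (29 tested), 15 rose and 5 fell (15 and 5 adjusted over the list alone, camera adjusted p = 0.00540, adjusted p = 0.600 with an estimated correlation). The genes noah-1 (5.16) and noah-2 (4.13), which encode extracellular matrix proteins of the embryonic epidermis, rose. Of the 28 autophagy and lysosome genes tested, 15 rose and 2 fell (15 and 2 adjusted over the list alone, camera adjusted p = 0.0144, adjusted p = 0.332 with an estimated correlation). Among them were epg-2 (4.09), an adaptor for the removal of P granule proteins in embryos, and the Atg8 gene lgg-1 (1.44).

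Among 30 DAF-16-induced genes, 16 rose and 3 fell (17 and 4 adjusted over the list alone, camera adjusted p = 0.00733, adjusted p = 0.600 with an estimated correlation). Examples were dod-3 (6.73) and hsp-16.48 (3.55), while daf-36 (-1.84) and the aquaporin gene aqp-1 (-3.07) fell. For DAF-16-repressed genes (17 tested), 3 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.994). Of the 198 innate immunity genes tested, 88 rose and 40 fell (89 and 41 adjusted over the list alone, camera adjusted p = 0.00520, adjusted p = 0.600 with an estimated correlation). Examples were clec-266 and the caenacin gene cnc-7 (6.37), of an antimicrobial peptide family. Among 61 neuropeptide genes, 22 rose and 2 fell (20 and 2 adjusted over the list alone, camera adjusted p = 0.0139, adjusted p = 0.820 with an estimated correlation). The peptide genes nlp-39 (6.97) and nlp-51 (4.24) rose. For intestine genes (30 tested), 4 rose and 14 fell (4 and 14 adjusted over the list alone, camera adjusted p = 0.0139, adjusted p = 0.820 with an estimated correlation). The acid phosphatase gene pho-1 (-3.58) and the intermediate filament gene ifc-2 (-2.61) fell. Of superoxide dismutase, catalase and phase II genes (62 tested), 25 rose and 6 fell (25 and 6 adjusted over the list alone). Camera adjusted p was 0.0411, and 0.657 with an estimated correlation. Of 28 lists camera called 11, of which calls ended with a minimum mean of 5 (superoxide dismutase, early embryo), no filter on low values (superoxide dismutase), quantile normalization (superoxide dismutase, neuropeptide, intestine), wt 1 and daf-2 1 left out (superoxide dismutase, neuropeptide) and 1 library left out (superoxide dismutase, neuropeptide).

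The largest rises with separate groups were clec-266 (9.0), mtl-1 (8.82), hch-1 (8.68), F48C1.9 (8.63), dpy-14 (8.50) and cnc-2 (7.40), and the largest falls were all collagen genes, col-167 (-8.89), col-147 (-8.70), col-133 (-8.41), col-12 (-8.34), col-146 (-8.28) and col-7 (-8.12).

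**Figure D3:**
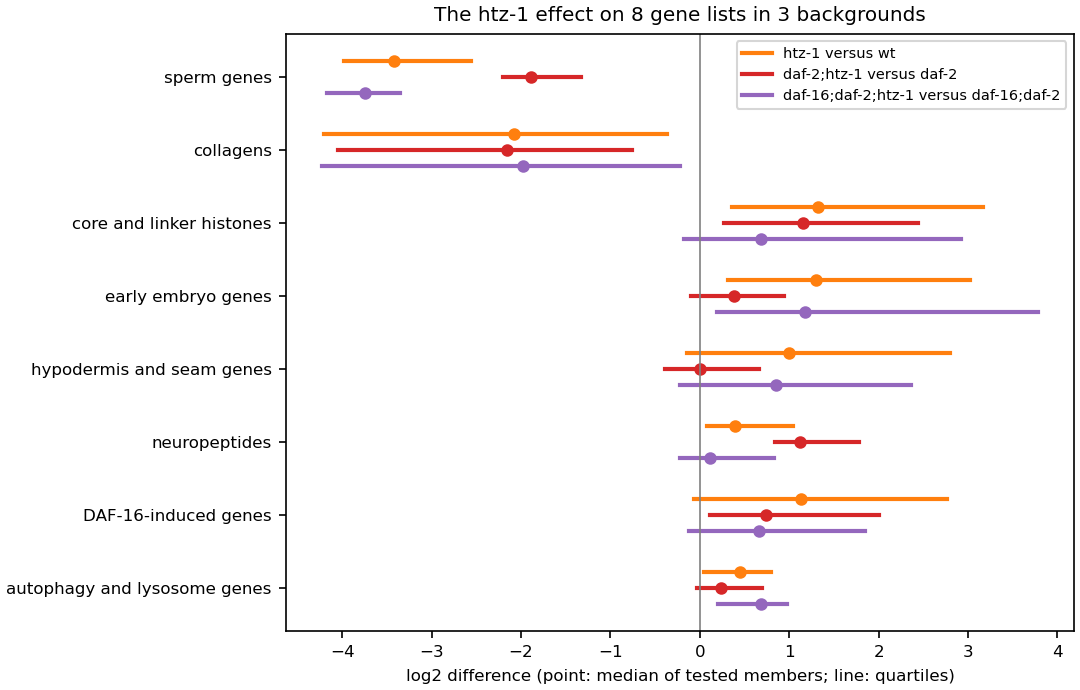
The log2 difference between libraries with and without the htz-1 allele (horizontal axis) for 8 gene lists (vertical axis) in the wt, daf-2 and daf-16;daf-2 backgrounds, with the median of the tested members as a point and their quartiles as a line. The sperm and collagen medians lie below 0 in all 3 backgrounds, and the early embryo and hypodermis medians lie nearer to 0 in the daf-2 background than in the other 2.

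The comparison of daf-2;htz-1 with daf-2 asked what the htz-1 allele changes where insulin/IGF-1 signalling is reduced. The value of mtl-1 rose further, from 12.87 ± 0.32 to 15.46 ± 0.20 (SD, n = 4), by 2.59 ± 0.88 (SE), adjusted p = 0.0204, a call that ended without batch 1, 2 or 4 (values from 2.55 to 2.68). All 4 daf-2;htz-1 libraries (15.21 to 15.65) lay above the 4 daf-2 libraries (12.56 to 13.31). The SE was widened by replicate 3 of daf-16;daf-2;htz-1, a group not compared here, and the call held without batch 3. The values of sod-3 (0.45, adjusted p = 0.610), dod-17 (0.53), ins-7 (0.97), hsp-12.6 (-0.08), daf-16 (-0.14) and htz-1 (0.33, adjusted p = 0.0946) were not called. However, ins-7 was called without batch 2 (1.5) or daf-2 2 (1.41) and with array weights (1.18), htz-1 without daf-2 4 (0.43) and with quantile normalization (0.50) or array weights (0.32), and sod-3 in a fit of only these 8 libraries (0.45). In all, 2950 genes were higher and 2918 lower, 1904 and 1844 of them by at least 1 log2 unit.

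Of the 61 neuropeptide genes tested, 48 rose and 1 fell (52 and 1 adjusted over the list alone, camera adjusted p = 2.1e-12, adjusted p = 0.309 with an estimated correlation). Examples were nlp-39 (6.46) and flp-1 (2.45). Among 30 neuronal genes, 14 rose and 0 fell (14 and 1 adjusted over the list alone, camera adjusted p = 0.0101, adjusted p = 0.410 with an estimated correlation). They included unc-31 (2.78) and the synaptobrevin gene snb-1 (1.25). For core and linker histone genes (59 tested), 33 rose and 2 fell (36 and 2 adjusted over the list alone, camera adjusted p = 3.9e-10, adjusted p = 0.309 with an estimated correlation). The core histone genes his-61 (3.49) and his-47 (3.58) rose. Of the 131 collagen genes tested, 9 rose and 89 fell (10 and 95 adjusted over the list alone, camera adjusted p = 3.0e-18, adjusted p = 0.309 with an estimated correlation). Among 88 sperm genes, 1 rose and 79 fell (1 and 80 adjusted over the list alone, camera adjusted p = 1.1e-22, adjusted p = 0.309 with an estimated correlation). The falls included col-81 (-4.52), col-129 (-4.53), sss-1 (-2.46) and the sperm channel gene spe-41 (-2.81). For early embryo genes (21 tested), 4 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.434). Of the 121 cytochrome P450 and UDP-glucuronosyltransferase genes tested, 50 rose and 17 fell (54 and 18 adjusted over the list alone, camera adjusted p = 7.6e-04, adjusted p = 0.597 with an estimated correlation). The cytochrome genes cyp-13A5 (4.1) and cyp-14A5 (2.78) rose.

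Among 26 heat shock genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 0.0237, adjusted p = 0.383 with an estimated correlation). For DAF-16-induced genes (30 tested), 14 rose and 3 fell (15 and 3 adjusted over the list alone, camera adjusted p = 0.0159, adjusted p = 0.567 with an estimated correlation). The genes aqp-1 (-3.43) and daf-36 (-1.42) fell. Of the 48 oogenesis and germline genes tested, 0 rose and 8 fell (0 and 6 adjusted over the list alone, camera adjusted p = 0.0148, adjusted p = 0.905 with an estimated correlation). The germline genes mex-6 (-1.14) and glh-1 (-0.87), a Vasa helicase of P granules, fell. Camera also called, with numbers of higher and lower members, superoxide dismutase, catalase and phase II (26 and 7 of 62, 28 and 7 adjusted over the list alone, camera adjusted p = 7.4e-04), innate immunity (76 and 39 of 198, 78 and 43 adjusted over the list alone, camera adjusted p = 0.0264), insulin-like peptide (9 and 0 of 20, 9 and 1 adjusted over the list alone, camera adjusted p = 0.0123), DNA replication and cell cycle (0 and 6 of 34, 0 and 3 adjusted over the list alone, camera adjusted p = 0.0430), autophagy and lysosome (12 and 3 of 28, 12 and 4 adjusted over the list alone, camera adjusted p = 0.0293) and ribosomal protein (1 and 0 of 78, 0 and 0 adjusted over the list alone, camera adjusted p = 0.0264) genes. None was kept with an estimated correlation (adjusted p = 0.309, 0.687, 0.537, 0.905, 0.309 and 0.905). Camera called 15 of 28 lists, and calls ended with batch as a block (DNA replication list, adjusted p = 0.0566), a minimum mean of 5 (insulin-like peptide, DNA replication), no filter on low values (immunity), centring (autophagy, DNA replication), quantile normalization (oogenesis, DNA replication), wt 1 and daf-2 1 left out (immunity, oogenesis, DNA replication) and 1 library left out (immunity, oogenesis, DNA replication, ribosomal, heat shock, autophagy).

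The largest rises with separate groups were F33H12.7 (8.43), D1086.9 (8.37), F56A4.3 (7.91), F48C1.9 (7.09), WBGene00014732 (7.04) and nlp-39 (6.46), of which WBGene00014732 is annotated as a pseudogene. The largest falls were again collagen genes, col-117 (-7.58), col-133 (-6.94), col-147 (-6.74), col-161 (-6.43), col-146 (-6.34) and col-12 (-6.22). The values of D1086.9, col-146 and col-12 in daf-2 replicate 1 stood apart from the other daf-2 libraries.

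The comparison of daf-16;daf-2;htz-1 with daf-16;daf-2 asked what the htz-1 allele changes where DAF-16 is also mutated. The gene hch-1 rose by 8.41 ± 0.65 (SE), adjusted p = 1.5e-10, clec-266 by 8.40 and dpy-14 by 7.77. The DAF-16 target mtl-1 was called higher at 3.60 ± 0.88 (SE), adjusted p = 0.00137, with a group value of 9.48 ± 3.44 (SD, n = 4) that rested on the library labelled replicate 3, and its value without that library was 1.92, adjusted p = 6.1e-06. For sod-3 the difference was -1.08, adjusted p = 0.178, and without replicate 3 it was called at -2.23, adjusted p = 6.5e-06 (with array weights at -1.81). The value of dod-17 fell by 1.99, adjusted p = 2.9e-05, and htz-1 rose by 0.63 ± 0.16 (SE), adjusted p = 0.00183. The daf-16 value was -0.55, adjusted p = 0.0304, a call that ended without batch 1 or 4, daf-16;daf-2 1 or 3, or daf-16;daf-2;htz-1 1, and with centring, quantile normalization and a fit of only these 8 libraries (values from -0.64 to -0.23), while hsp-12.6 (-0.35) and ins-7 (0.45) were not called. In all, 3487 genes were higher and 3514 lower, 2110 and 2406 of them by at least 1 log2 unit.

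Among 88 sperm genes, 0 rose and 85 fell (0 and 85 adjusted over the list alone, camera adjusted p = 8.5e-34, adjusted p = 0.304 with an estimated correlation). For collagen genes (131 tested), 18 rose and 79 fell (18 and 79 adjusted over the list alone, camera adjusted p = 1.4e-07, adjusted p = 0.711 with an estimated correlation). The falls included sss-1 (-4.89), msp-59 (-4.38), col-81 (-6.65) and col-129 (-6.38). Of the 21 early embryo genes tested, 11 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 2.4e-04, adjusted p = 0.355 with an estimated correlation). Examples were sdz-28 (4.21) and the zygotic gene vet-6 (6.03). Among 59 core and linker histone genes, 30 rose and 6 fell (30 and 6 adjusted over the list alone, camera adjusted p = 4.6e-05, adjusted p = 0.711 with an estimated correlation). The linker histone gene his-24 (4.35) and the core histone gene his-58 (3.12) rose, and the list's mean in replicate 3 stood apart from the other daf-16;daf-2;htz-1 libraries (7.2 against a median of 7.64). For autophagy and lysosome genes (28 tested), 19 rose and 1 fell (20 and 1 adjusted over the list alone, camera adjusted p = 9.1e-05, adjusted p = 0.0611 with an estimated correlation). Of the 29 hypodermis and seam genes tested, 14 rose and 4 fell (14 and 4 adjusted over the list alone, camera adjusted p = 0.00973, adjusted p = 0.711 with an estimated correlation). The genes noah-1 (4.02) and wrt-10 (5.34), a Hedgehog-related gene, rose.

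Among 30 DAF-16-induced genes, 13 rose and 5 fell (14 and 5 adjusted over the list alone, camera adjusted p = 0.0349, adjusted p = 0.711 with an estimated correlation). The hsp-16.48 pair rose (3.55 each), and daf-36 (-1.56) and aqp-1 (-2.28) fell. Also called by camera, with numbers of higher and lower members, were intestine (3 and 17 of 30, 3 and 18 adjusted over the list alone, camera adjusted p = 0.0235), DNA replication and cell cycle (11 and 2 of 34, 11 and 2 adjusted over the list alone, camera adjusted p = 0.0493) and ribosomal protein (0 and 8 of 78, 0 and 2 adjusted over the list alone, camera adjusted p = 0.00973) genes. Each call had adjusted p = 0.711 with an estimated correlation. Of 28 lists camera called 10, of which calls ended with batch as a block (DNA replication list, adjusted p = 0.0548), a minimum mean of 5 (DAF-16-induced), no filter on low values (DAF-16-induced, DNA replication), centring (DAF-16-induced, DNA replication), quantile normalization (DAF-16-induced, intestine, ribosomal), daf-16;daf-2;htz-1 replicate 3 left out (DAF-16-induced list, adjusted p = 0.217, median 0.28 from 0.66; hypodermis list, adjusted p = 0.0519, median 0.50 from 0.85; ribosomal list, adjusted p = 0.217, median -0.26 from -0.48) and 1 library left out (intestine, DNA replication, ribosomal).

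The largest rises with separate groups were hch-1 (8.41), clec-266 (8.40), dpy-14 (7.77), F48C1.9 (6.95), C08F1.10 (6.71) and cnc-2 (6.58). The largest falls were col-62 (-9.26), col-7 (-9.15), col-126 (-8.84), col-146 (-8.56), col-147 (-8.37) and col-127 (-8.37). The split of 3487 higher and 3514 lower depended on scaling, with 4781 and 2728 when each library was centred on its median (a shift of the median of all genes by 0.24) and 4610 and 3043 with quantile normalization (a shift of 0.15).

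The htz-1 effects in the 3 backgrounds share no libraries. Of the genes higher in htz-1 than in wt, 2594 were also higher in daf-16;daf-2;htz-1 than in daf-16;daf-2 (922 expected for independent lists) and 2004 in daf-2;htz-1 than in daf-2 (780 expected). Of the lower genes, the shared numbers were 2787 (862 expected) and 2259 (716 expected). The correlation across genes was 0.92 between the wt and daf-16;daf-2 backgrounds, 0.78 between wt and daf-2, and 0.71 between daf-2 and daf-16;daf-2. Simulated unchanged groups gave -0.77 to 0.78, but mean covariances near 0 against 2.22, 1.32 and 1.27. The effect of daf-16 in daf-2 went against the htz-1 effect (correlation -0.46), and 746 of the 1397 genes lower in daf-16;daf-2 than in daf-2 were higher in htz-1 than in wt (369 expected). The daf-2 and htz-1 effects, which share the wt libraries, had a correlation of 0.42 (simulated mean 0.45, 0.33 with the wt libraries split), and their covariance was 0.45 against 0.05 simulated. Of the genes higher in daf-2, 622 were higher in htz-1 (246 expected), and with the wt libraries split 353 were shared on average (143 expected).

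The comparison of daf-16;daf-2;htz-1 with daf-2;htz-1 asked which transcripts depended on DAF-16 in the presence of the htz-1 allele. The DAF-16 targets mtl-1 (-5.98 ± 0.88 (SE), adjusted p = 1.4e-05) and sod-3 (-5.55 ± 0.65 (SE), adjusted p = 7.7e-07) fell, and without replicate 3 of daf-16;daf-2;htz-1 their differences were -7.66 and -6.70. The value of dod-17 rose by 1.77 ± 0.34 (SE), adjusted p = 3.4e-04, ilys-5 by 5.76 and the intestinal peptide transporter gene pept-1 by 3.77. The yolk protein genes vit-1 (3.70) and vit-5 (1.94) rose. In all, 1853 genes were higher and 2518 lower, 1074 and 1730 of them by at least 1 log2 unit. The values of hsp-12.6 (-0.96) and ins-7 (0.33) were not called, but hsp-12.6 was called without replicate 3 (-1.22, adjusted p = 0.0387) and with array weights (-1.38).

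For DAF-16-induced genes (30 tested), 2 rose and 17 fell (2 and 18 adjusted over the list alone, camera adjusted p = 1.2e-05, adjusted p = 0.313 with an estimated correlation). Here daf-36 (0.84) and the metallothionein gene mtl-2 (1.12) rose, a call for mtl-2 that ended without batch 1, 2 or 4, daf-16;daf-2;htz-1 1 or 4, or daf-2;htz-1 2 or 3 (values from 0.89 to 1.18). Of the 17 DAF-16-repressed genes tested, 8 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 4.9e-05, adjusted p = 0.229 with an estimated correlation). The genes dod-24 (4.64) and pept-1 rose, and the claudin-like gene cld-9 fell (-0.80), a call that ended without batch 1, 2 or 4, daf-2;htz-1 1, 2, 3 or 4, or daf-16;daf-2;htz-1 2 or 4, and with no filter on low values, centring and no intensity trend (values from -0.85 to -0.60). Among 6 vitellogenin genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.00109, adjusted p = 0.382 with an estimated correlation). For neuropeptide genes (61 tested), 0 rose and 40 fell (0 and 47 adjusted over the list alone, camera adjusted p = 9.9e-10, adjusted p = 0.313 with an estimated correlation). Examples were flp-34 (-3.77) and flp-9 (-1.51). Of the 20 insulin-like peptide genes tested, 1 rose and 11 fell (2 and 12 adjusted over the list alone, camera adjusted p = 0.00416, adjusted p = 0.382 with an estimated correlation). They included ins-26 (-3.40) and ins-30 (-2.94). Among 20 ER chaperone and sensor genes, 9 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 0.00124, adjusted p = 0.382 with an estimated correlation). The disulfide isomerase genes pdi-2 (1.26) and pdi-6 (1.03) rose.

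For early embryo genes (21 tested), 11 rose and 2 fell (12 and 2 adjusted over the list alone, camera adjusted p = 7.6e-04, adjusted p = 0.326 with an estimated correlation). The genes lin-32 (3.91) and nhr-2 (1.64), a nuclear receptor gene, rose. Of the 29 hypodermis and seam genes tested, 11 rose and 4 fell (12 and 4 adjusted over the list alone, camera adjusted p = 0.00105, adjusted p = 0.382 with an estimated correlation). Here noah-1 rose by 4.14 and noah-2 by 4.03. Among 30 intestine genes, 13 rose and 4 fell (15 and 4 adjusted over the list alone, camera adjusted p = 1.1e-04, adjusted p = 0.382 with an estimated correlation). The aspartyl protease gene asp-1 (2.81) and vha-6 (2.11) rose. For DNA replication and cell cycle genes (34 tested), 10 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 1.5e-04, adjusted p = 0.543 with an estimated correlation). The cyclin B gene cyb-3 (1.12) rose. Camera also called, with numbers of higher and lower members, sperm (1 and 35 of 88, 1 and 38 adjusted over the list alone, camera adjusted p = 1.5e-06), superoxide dismutase, catalase and phase II (3 and 26 of 62, 3 and 26 adjusted over the list alone, camera adjusted p = 1.1e-04), innate immunity (60 and 44 of 198, 62 and 55 adjusted over the list alone, camera adjusted p = 0.0423), oogenesis and germline (7 and 0 of 48, 1 and 0 adjusted over the list alone, camera adjusted p = 0.00391) and cytochrome P450 and UDP-glucuronosyltransferase (15 and 42 of 121, 16 and 43 adjusted over the list alone, camera adjusted p = 0.00416) genes. None was kept with an estimated correlation (adjusted p = 0.595, 0.313, 0.595, 0.722 and 0.595). Camera called 15 of 28 lists, and calls ended with a minimum mean of 5 (early embryo), no filter on low values (immunity), centring (immunity), quantile normalization (immunity, oogenesis), daf-16;daf-2;htz-1 replicate 3 left out (immunity list, adjusted p = 0.258, median 0.02 from 0.04) and 1 library left out (immunity, oogenesis).

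The largest rises with separate groups were hch-1 (6.31), cld-1 (6.25), F55G11.2 (6.11), clec-10 (5.80), ilys-5 (5.76) and clec-3 (5.72), of which cld-1 encodes a claudin-like protein. The largest falls were H39E23.3 (-9.90), F56D6.9 (-8.69), spp-9 (-7.70), D1086.9 (-7.49), clec-18 (-7.45) and scl-20 (-7.43), and in all 6 of these the library labelled replicate 3 lay above the other 3 libraries of its group, so that H39E23.3 was at -11.62 and F56D6.9 at -11.09 without it. The counts without replicate 3 were 1778 higher and 2430 lower, with array weights 3525 and 4235, and as low as 1187 higher without batch 2 and 1407 lower without batch 4. In the order of the comparisons above, the 2 groups did not overlap for 12.7, 24.9, 44.6, 38.8, 40.1 and 29.9% of genes, against 2.86% by chance.

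**Figure D4:**
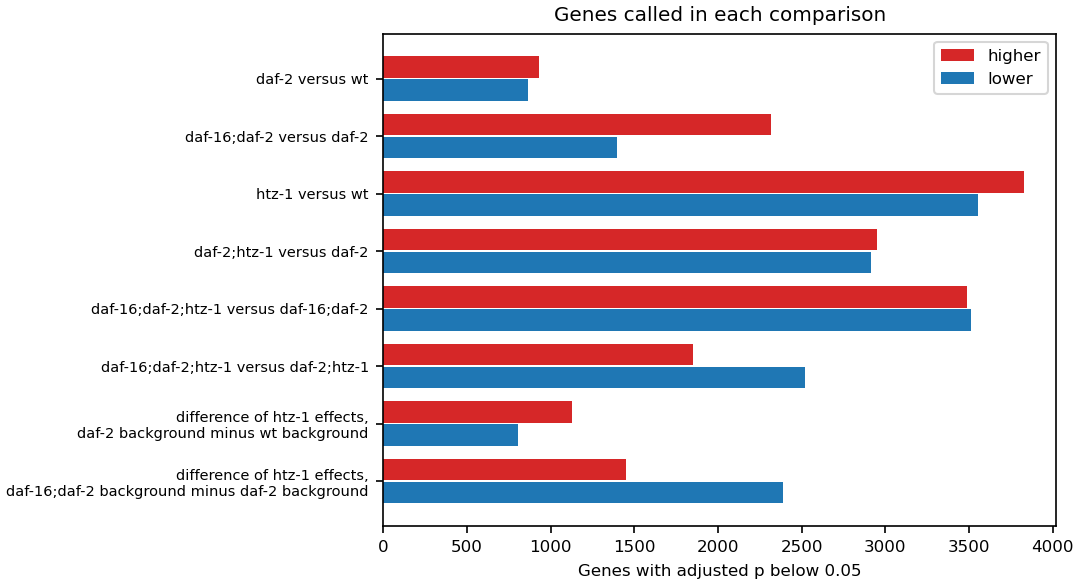
Number of genes with limma adjusted p below 0.05 (horizontal axis, bars from 0) that were higher (red) or lower (blue) in each of the 6 pairwise comparisons and the 2 differences of the htz-1 effect (vertical axis), of 14482 genes tested. The htz-1 effect in the wt background has the longest bars.

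Whether the htz-1 effect differed between backgrounds was tested as a difference of differences. Between the daf-2 and wt backgrounds, 1126 genes had a more positive and 806 a more negative effect in daf-2. The most negative differences were hch-1 (-7.62 ± 0.92 (SE), adjusted p = 6.9e-06 for the difference), clec-266 (-7.2), pud-3 (-7.16) and pud-4 (-6.45). The proteins of the last 2 genes are known to be more abundant in daf-2 mutants. The most positive differences were D1086.9 (7.91), F56A4.3 (6.66), F33H12.7 (6.07) and irld-35 (5.74). Of the 88 sperm genes tested, 35 had a more positive and 1 a more negative effect (67 and 1 adjusted over the list alone, camera adjusted p = 9.2e-17, adjusted p = 0.802 with an estimated correlation). Among 21 early embryo genes, 0 had a more positive and 11 a more negative effect (0 and 12 adjusted over the list alone, camera adjusted p = 3.6e-05, adjusted p = 0.550 with an estimated correlation). For hypodermis and seam genes (29 tested), 0 had a more positive and 9 a more negative effect (1 and 10 adjusted over the list alone, camera adjusted p = 3.3e-05, adjusted p = 0.550 with an estimated correlation). Of the 61 neuropeptide genes tested, 8 had a more positive and 0 a more negative effect (8 and 0 adjusted over the list alone, camera adjusted p = 5.4e-05, adjusted p = 0.802 with an estimated correlation). Also called by camera, with numbers of members with a more positive and a more negative effect, were muscle (5 and 1 of 33, 5 and 1 adjusted over the list alone, camera adjusted p = 0.00543), histone (0 and 6 of 59, 0 and 5 adjusted over the list alone, camera adjusted p = 0.0161), oogenesis and germline (0 and 1 of 48, 0 and 1 adjusted over the list alone, camera adjusted p = 0.0442), DNA replication and cell cycle (0 and 1 of 34, 0 and 1 adjusted over the list alone, camera adjusted p = 0.0123) and ribosomal protein (2 and 0 of 78, 0 and 0 adjusted over the list alone, camera adjusted p = 7.4e-04) genes. None was kept with an estimated correlation (adjusted p = 0.835 for oogenesis, else 0.802). Of 28 lists camera called 9, of which calls ended with centring (oogenesis), wt 1 and daf-2 1 left out (histone) and 1 library left out (histone, oogenesis, DNA replication, muscle, ribosomal). The counts were as low as 278 and 350 without batch 4, and 1905 were more positive with array weights.

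Between the daf-16;daf-2 and daf-2 backgrounds, 1449 genes had a more positive and 2389 a more negative htz-1 effect in daf-16;daf-2. The genes hch-1 (7.35 ± 0.92 (SE), adjusted p = 8.4e-06), clec-266 (6.61), F45D11.14 (6.29) and the F-box gene fbxc-51 (6.16) had the most positive differences. The most negative were D1086.9 (-6.72), WBGene00014732 (-5.62), F33H12.7 (-5.25) and WBGene00020598 (-5.21), the last also annotated as a pseudogene. Among 88 sperm genes, 1 had a more positive and 61 a more negative effect (1 and 75 adjusted over the list alone, camera adjusted p = 9.4e-16, adjusted p = 0.489 with an estimated correlation). For early embryo genes (21 tested), 10 had a more positive and 0 a more negative effect (11 and 1 adjusted over the list alone, camera adjusted p = 1.0e-05, adjusted p = 0.259 with an estimated correlation). Of the 29 hypodermis and seam genes tested, 10 had a more positive and 0 a more negative effect (10 and 0 adjusted over the list alone, camera adjusted p = 6.6e-04, adjusted p = 0.489 with an estimated correlation). Among 61 neuropeptide genes, 0 had a more positive and 26 a more negative effect (1 and 33 adjusted over the list alone, camera adjusted p = 2.0e-06, adjusted p = 0.489 with an estimated correlation). For H2A.Z deposition complex genes (15 tested), 2 had a more positive and 0 a more negative effect (1 and 0 adjusted over the list alone, camera adjusted p = 0.0132, adjusted p = 0.489 with an estimated correlation). Camera also called, with numbers of members with a more positive and a more negative effect, oogenesis and germline (13 and 0 of 48, 13 and 0 adjusted over the list alone, camera adjusted p = 3.7e-06), DNA replication and cell cycle (13 and 0 of 34, 13 and 0 adjusted over the list alone, camera adjusted p = 6.6e-06), autophagy and lysosome (9 and 0 of 28, 9 and 0 adjusted over the list alone, camera adjusted p = 0.00395), muscle (1 and 10 of 33, 1 and 11 adjusted over the list alone, camera adjusted p = 0.0209) and ribosomal protein (0 and 5 of 78, 0 and 1 adjusted over the list alone, camera adjusted p = 3.7e-06) genes. Adjusted p was 0.769, 0.652, 0.259, 0.769 and 0.769 with an estimated correlation. Camera called 10 of 28 lists, and calls ended with daf-16;daf-2;htz-1 replicate 3 left out (muscle list, adjusted p = 0.0647, median -0.41 from -0.46), wt 1 and daf-2 1 left out (muscle) and 1 library left out (muscle). The split of 1449 and 2389 became 2256 and 1778 when libraries were centred (a shift of the median of all genes by 0.28) and 2044 and 1971 with quantile normalization (a shift of 0.16), 2590 and 3683 with array weights, and was as low as 757 without batch 3 and 1506 without batch 4.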

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

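Chosen only after the result was seen were the tests of the library labelled daf-16;daf-2;htz-1 replicate 3, of composition and stage and of the DAF-16 target genes in htz-1, and the look at htz-1 shares in the splits, while the counts of splits were fixed beforehand.

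In each of the 6 pairwise comparisons 1 of 35 splits of the 8 libraries ignoring batch, the real split, gave as many genes. This share was not adjusted for 6 tests. The real count and the highest of the other splits were 1793 and 280 for daf-2 against wt, 3716 and 342 for daf-16;daf-2 against daf-2, 7382 and 1013 for htz-1 against wt, 5868 and 1160 for daf-2;htz-1 against daf-2, 7001 and 1221 for daf-16;daf-2;htz-1 against daf-16;daf-2 and 4371 and 363 for daf-16;daf-2;htz-1 against daf-2;htz-1. Of the 8 splits that part all 4 batch pairs, the highest other counts were 10, 2, 1, 750, 1221 and 305 in the same order, and 8 splits are too few for a share under 0.05. For the difference of the htz-1 effect between the daf-2 and wt backgrounds, 4 of 100 drawn splits, the real one included, gave as many genes (real 1932, highest other 6793), and between the daf-16;daf-2 and daf-2 backgrounds 3 of 100 (real 3838, highest other 5898). All 94 and 95 splits that mixed libraries with and without the htz-1 allele in both backgrounds, among them the 38 and 35 with equal shares of htz-1 libraries in the 2 contrasts, called 0 genes, and all 5 and 4 that mixed them in 1 background called genes. The counts thus follow a structure of the samples, the htz-1 effect, and chance was not excluded for these 2 or the 6.

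A library far from the other 3 of its group was found for 28 of 454 sets of a gene's values and 6 of 144 sets of list means, by Dixon's ratio. Chance alone gives about 1 in 20 groups (22.7 of the gene sets). Each such value is given against the median of the other 3 libraries. In the library labelled daf-16;daf-2;htz-1 replicate 3, the values were aqp-1 (9.65 against 7.16), spp-9 (7.64 against 1.67), D1086.9 (7.01 against 1.24), clec-18 (6.78 against 2.01), scl-20 (5.87 against 1.96), nhr-2 (8.83 against 8.08) and the mean of core and linker histones (7.2 against 7.64). In daf-2 replicate 1, the values were his-16 (4.00 against 2.02), D1086.9 (4.19 against 1.21), col-146 (9.85 against 12.83), col-12 (10.54 against 13.19) and the mean of collagens (8.38 against 9.59). Of the other libraries, 15 had 1 or 2 such values each and 7 had 0. In daf-16;daf-2 replicate 1 they were hsp-12.6 (4.56 against 3.35) and the mean of vitellogenins (18.04 against 16.58). For daf-16;daf-2 replicate 3 they were nhr-2 (5.44 against 6.04) and noah-1 (6.63 against 6.29). In daf-16;daf-2;htz-1 1 they were daf-16 (8.47 against 9.54) and the mean of vitellogenins (17.09 against 18.27). For daf-16;daf-2;htz-1 4 they were hch-1 (10.13 against 10.52) and col-7 (4.50 against 5.08). In wt 1 they were tts-1 (4.33 against 2.79) and col-12 (11.53 against 13.44). For wt 2 they were nlp-51 (3.33 against 2.42) and the mean of proteasome subunits (11.29 against 11.51). In wt 3 they were daf-16 (11.26 against 10.59) and hsp-3 (14.04 against 13.23). For daf-16;daf-2 4 it was the mean of DAF-16-repressed genes (11.17 against 11.38). In daf-2 2 it was daf-36 (10.04 against 9.12). For daf-2;htz-1 1 it was clec-10 (3.09 against 2.26). In daf-2;htz-1 2 it was pdi-6 (12.003 against 11.60). For daf-2;htz-1 4 it was htz-1 (11.28 against 11.35). In htz-1 1 it was col-167 (5.85 against 4.41). For htz-1 3 it was dod-3 (13.67 against 13.85). In wt 4 it was lin-32 (1.98 against 1.46).

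The library labelled daf-16;daf-2;htz-1 replicate 3 held DAF-16 target transcripts at high levels, and 3 explanations were tested. A swap within the series needs another library out of place, and 4 of the others lay closest to the mean of another group, but 0 libraries of the other 5 groups lay closest to the mean of the other 3 daf-16;daf-2;htz-1 libraries, which argues against a partner. A wrongly labelled htz-1 library is argued against by 75.6% (59 of 78) of the genes that were lower by 4 log2 units or more in the other 3 libraries than in daf-2;htz-1, which lay above the highest htz-1 library, although its distance to the htz-1 mean (0.743) was below that to its own group (0.812). A single share of daf-2;htz-1 RNA stays open, since the shares these genes imply had quartiles of 14.6% and 51.7%, a ratio of 3.54 between the bounds set for and against it, and a second definition, 3 log2 units or more both here and in daf-16;daf-2 against daf-2 (57 genes), gave 77.2% and 3.49. A wrong label from outside the series or a real difference between animals could also remain, and no biological explanation was tested.

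In the htz-1 libraries sperm and collagen genes were lower and embryo genes higher. A shift common to all genes is argued against, since the collagen median lay -2.01 from that of all genes in the daf-16;daf-2 background, the smallest gap. That median was -1.98, and -0.78 with no filter. A difference in stage at collection stays open. Libraries wt 1 and daf-2 1 deviated from the rest of their groups along the htz-1 effect in daf-16;daf-2 (r = 0.455 and 0.654 across genes, which are not independent replicates). Both were chosen on seeing the data and share batch 1 (r = 0.513 between them), so stage and batch are not separated. Their deviations had medians of -0.66 and -1.54 for sperm genes, -1.13 and -1.27 for collagen genes and -0.07 and 0.38 for early embryo genes. Stage, composition and an effect of H2A.Z on these genes may all contribute, and the values do not separate them.

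The gene mtl-1 and other DAF-16-induced genes were higher in htz-1 than in wt, while sod-3 was not called. RNA of daf-2;htz-1 animals in the htz-1 libraries is argued against, because 32.1% (25 of 78) of the DAF-16-dependent genes implied a share under 10% of the 29.1% that mtl-1 implied, and sod-3 implied -1.14%. The 1397 genes lower in daf-16;daf-2 than in daf-2 had a median of 0.62 in htz-1 against wt, 0.66 above expression-matched genes. A raised DAF-16-dependent programme stays open, since daf-2 1, which deviated along the htz-1 effect, helped choose these genes (891 without it). No group carries daf-16 and htz-1 without daf-2. Without replicate 3, daf-16;daf-2;htz-1 lay below htz-1 for mtl-1 (-5.82, adjusted p = 4.8e-12), F56D6.9 (-6.95) and fipr-26 (-2.71), while tts-1 (-1.32) and dod-3 (-1.70) were not called. These groups also differ in daf-2, whose allele raised mtl-1 and F56D6.9. The htz-1 rise of F56D6.9 was 7.28, and the values fit a need for DAF-16 in part of both rises. For the other genes a rise that does not need it stays open.

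Named genes and called lists whose htz-1 effect differed between backgrounds by the test of the difference itself (limma or camera, adjusted p below 0.05) are given as log2 differences, for lists as the median. In daf-2 the effect was more positive than in wt for D1086.9 (7.91), F56A4.3 (6.66), F33H12.7 (6.07), irld-35 (WBGene00021222) (5.74), WBGene00014732 (4.37), clec-210 (3.24), cyp-13A5 (2.5), col-129 (2.42), col-81 (2.22), dod-17 (2.21), thn-2 (2.19), msp-65 (2.17), msp-59 (2.1), sss-1 (1.32) and hsp-43 (0.56). It was more negative for hch-1 (-7.62), clec-266 (-7.2), pud-3 (-7.16), pud-4 (-6.45), mtl-1 (-6.23), dpy-14 (-5.89), noah-1 (-5.28), dod-3 (-4.83), hil-7 (-4.29), noah-2 (-4.28), lin-32 (-3.86), cnc-2 (-2.75), cnc-7 (-2.62), epg-2 (-2.58), sdz-28 (-2.13), gst-32 (-1.65), hsp-16.48 (WBGene00002019) (-1.23) and hsp-16.48 (WBGene00002020) (-1.23). Lists with a more positive effect were sperm genes (1.48), neuropeptides (0.71), muscle genes (0.58) and ribosomal proteins (0.53), and those with a more negative effect were early embryo genes (-1.15), hypodermis and seam genes (-0.71), DNA replication and cell cycle genes (-0.25), core and linker histones (-0.20) and oogenesis and germline genes (-0.15). In daf-16;daf-2 the effect was more positive than in daf-2 for hch-1 (7.35), clec-266 (6.61), F45D11.14 (6.29), fbxc-51 (6.16), C08F1.10 (5.24), dpy-14 (5.16), vet-6 (4.66), wrt-10 (4.52), noah-1 (4.14), his-24 (4.03), epg-2 (2.66), sdz-28 (2.65), cdt-1 (1.54), hsp-16.48 (WBGene00002019) (1.24), hsp-16.48 (WBGene00002020) (1.24), mex-6 (1.11), atg-4.2 (0.84) and cyb-2.2 (0.50), and more negative for D1086.9 (-6.72), WBGene00014732 (-5.62), F33H12.7 (-5.25), WBGene00020598 (-5.21), clec-210 (-4.32), col-62 (-4.31), F56A4.3 (-3.62), col-126 (-3.52), col-7 (-3.25), thn-2 (-2.91), col-127 (-2.71), dod-17 (-2.52), sss-1 (-2.43), msp-59 (-2.31), rpl-42 (-2.28), col-81 (-2.13), col-129 (-1.85), cyp-14A5 (-1.65), ins-3 (-1.37), rpl-11.2 (-0.77) and hsp-43 (-0.66). The lists were early embryo genes (1.36), hypodermis and seam genes (0.68), DNA replication and cell cycle genes (0.54), oogenesis and germline genes (0.54), H2A.Z deposition complexes (0.51) and autophagy and lysosome genes (0.29) on the positive side and sperm genes (-1.80), neuropeptides (-1.11), ribosomal proteins (-0.83) and muscle genes (-0.46) on the negative side. With an estimated correlation no list call held (adjusted p = 0.550 to 0.835 for the first difference and 0.259 to 0.769 for the second). The report gives the other settings that ended calls, and without daf-2 1 the first histone median was 0.04 (not called).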

How the results depend on the processing

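With batch as a block, the 283 named gene values kept direction and side of the threshold. Of the 95 list calls 2 ended, DNA replication for the htz-1 effect in daf-2 and daf-16;daf-2. No count moved by over 1.5 times. The block is common to all groups, so a pairing of daf-2 with wt alone was not tested. No called named gene or list (by camera) reversed direction in any setting. The larger of the higher and lower counts became the smaller in at least 1 setting for every comparison but daf-16;daf-2;htz-1 against daf-2;htz-1, and only with centring and quantile normalization for daf-16;daf-2 against daf-2 and the second difference. Of the named gene values over the settings, 6080 kept their side of the threshold, 136 fell short of it and 14 passed it, and of the list values 1409 kept it and 238 fell short, 94 of them with an estimated correlation and 25 with fry. Other list calls ended with quantile normalization (12), wt 1 and daf-2 1 left out (10), a minimum mean of 5 (9), centring (7), no filter (6) and 1 library left out (73, of which daf-2 1 ended 9, daf-2 2 ended 8 and wt 1 ended 6). Medians of lists that stayed called moved by over 1.5 times in 77 values, 27 of them without 1 library (6 without daf-2 1). Robust variance changed no named gene call.

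Counts moved by over 1.5 times in these cases. With centring, the htz-1 effect was more positive in daf-16;daf-2 than in daf-2 for 2256 genes (1449 as deposited). Array weights, which down-weight libraries that vary more, gave 3525 higher and 4235 lower genes in daf-16;daf-2;htz-1 against daf-2;htz-1 (1853 and 2518 with equal weights), 1905 with a more positive effect in daf-2 than in wt (1126), and 2590 more positive and 3683 more negative in daf-16;daf-2 than in daf-2 (1449 and 2389). A fit of only the daf-2 and wt libraries gave 432 higher and 318 lower genes (931 and 862), with fewer residual degrees of freedom by construction. Without wt 1 and daf-2 1, 1484 genes were higher in daf-16;daf-2 than in daf-2 (2319). With the shared libraries split into 2 and 2, correlations of the daf-2 effect were -0.66 with the daf-16 effect and 0.33 and 0.18 with the htz-1 effects in wt and daf-2 (-0.85, 0.42 and 0.12 unsplit). With each batch or library left out, counts of higher and of lower genes ranged from 512 to 948 and 438 to 1135 for daf-2 against wt, 1283 to 2441 and 873 to 1427 for daf-16;daf-2 against daf-2, 1187 to 2205 and 1407 to 2682 for daf-16;daf-2;htz-1 against daf-2;htz-1, 278 to 1579 and 350 to 859 for the difference between daf-2 and wt, and 757 to 1759 and 1506 to 2610 for that between daf-16;daf-2 and daf-2. For the other settings the cause was not tested. Depth is unknown, so which low values reflect few reads was not determined.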

Other observations

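The gene classes below, the contrast of daf-16;daf-2 with wt and their tests were chosen only after the result was seen, while the tests of the X chromosome and of embryonic transcription factors were fixed before. Among 109 gene classes with at least 10 tested members, defined by the letters of the gene symbol, the F-box B (fbxb) genes, which encode F-box proteins of a large nematode family, stood out. In htz-1 against wt 36 of 37 rose (median 3.00, camera adjusted p = 2.8e-15, adjusted p = 0.0338 with an estimated correlation), in daf-16;daf-2;htz-1 against daf-16;daf-2 37 of 37 (median 3.51, adjusted p = 0.00649 with an estimated correlation) and in daf-2;htz-1 against daf-2 13 of 37 (median 0.90, adjusted p = 0.783 with an estimated correlation). Their htz-1 effect was more negative in daf-2 than in wt for 29 members (median -2.24, adjusted p = 0.00442 with an estimated correlation) and more positive in daf-16;daf-2 than in daf-2 for 34 (median 2.88, adjusted p = 0.00184 with an estimated correlation). These genes have similar copies whose reads could be shared, so single members are uncertain.

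Embryos inside the animals could carry the embryo transcripts, and embryonic patterning transcription factors were tested for this. Of 34 tested, 22 rose and 1 fell in htz-1 against wt (median 1.35, adjusted p = 1.4e-05, adjusted p = 0.0311 with an estimated correlation), with ceh-43 at 4.08, vab-3 at 3.92, mls-2 at 3.71 and cnd-1 at 3.65. In daf-16;daf-2;htz-1 against daf-16;daf-2, 24 rose and 1 fell (median 1.65, adjusted p = 0.0206 with an estimated correlation), and in daf-2;htz-1 against daf-2, 10 rose and 1 fell (median 0.40, adjusted p = 0.160 with an estimated correlation). The values needed for embryo transcripts were present, but transcription of these genes in adult tissue would give the same values, so more or older retained embryos remain a hypothesis.

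Genes on the X chromosome lay above expression-matched autosomal genes in all 3 htz-1 effects, by 0.161 in wt, 0.156 in daf-2 and 0.125 in daf-16;daf-2 on the log2 scale (1956 genes). The gap was 0.184 in daf-16;daf-2;htz-1 against daf-2;htz-1, 0.0546 in daf-16;daf-2 against daf-2 and -0.0751 in daf-2 against wt. Between daf-16;daf-2 and wt 116 genes were higher and 56 lower (134 and 55 with batch as a block). Rises included Y49E10.16 (4.1), the kinesin-like gene klp-4 (3.52), the polyadenylation factor gene pcf-11 (3.41) and irg-5 (3.19), and falls F56A4.3 (-3.63), the beta-galactosidase gene bgal-2 (-3.32), the aspartyl protease gene asp-8 (-2.71) and B0205.13 (-2.55).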
